A study of Mus musculus and Acomys cahirinus with 18 samples.

How the data were processed

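Kidney RNA was measured by sequencing in 18 libraries from 2 species, mouse and Acomys cahirinus, with 3 libraries in each of the sham, day 2 and day 5 groups of a species, grouped by the treatment and organism in the labels. Per the labels' protocols, males of both species had the left ureter obstructed or a sham operation, kidneys were perfused with cold saline and frozen, and total RNA was extracted. Reads were quantified with Salmon and compared with edgeR, per the submitters' processing notes, which also name the mouse build mm9. Versions, settings, the Acomys reference, filters and read totals are not given in the sources used here. The reference supplied here was of another build, so no coordinates are given.

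The authors deposited 4 tables, 1 for each obstructed group against the sham group of its species, with no values per library. Per the file headers each holds a log fold change, a mean expression (logCPM) and an FDR. The authors' fold changes were read as log2 values because that is how edgeR writes them, though the deposited tables do not state the base. The authors' logCPM is the log2 of mean CPM over their fit, and it was identical on both days for every gene listed on both, which points to 1 fit per species. The authors' FDR is an adjusted p-value, and every deposited entry is under 0.05. The direction, obstructed over sham, comes from the names of the tables. Mouse entries are genes with an Entrez ID and symbol. Acomys entries are numbered loci, some with a UniProt entry name and a mouse Entrez ID and symbol assigned by the authors; 644 of 1765 on day 2 and 1094 of 2500 on day 5 have no symbol. How transcripts of the same gene family were told apart in Acomys is not known, so values of close paralogues there are uncertain.

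No gene was refitted. Genes were counted as risen or fallen as listed at FDR under 0.05. Because genes short of the threshold are not in these tables, neither the count adjusted over the list alone nor an enrichment against all tested genes was computed, and the smallest listed absolute change was 0.73 and 0.72 in mouse and 0.95 and 0.93 in Acomys on days 2 and 5. The Acomys values belong to rises at logCPM above 6. The smallest falls listed at that expression were 1.47 and 1.14 in Acomys, against 0.74 and 0.72 in mouse. The comparisons, lists, tests, rule for named genes and 60 of 86 alternatives were fixed before the data were examined. The 29 gene lists cover tubule injury, proximal tubule, loop with distal tubule and collecting duct, podocyte, endothelium, matrix, collagen processing, myofibroblast and TGF-beta, matrix degradation, macrophage and monocyte, neutrophil, T and NK cell, B and plasma cell, cytokines and chemokines, complement, interferon response, cell cycle, arrest and senescence, kidney development, Wnt pathway, fatty acid oxidation, mitochondrial respiration, glycolysis, oxidative defence, immediate early genes, urothelium, adipocyte, adrenal and erythroid cells. The last 4 stand for other tissues that a dissected kidney could carry. With a panel of 24 genes they held 698 genes, matched by Entrez ID except 1 that had none. Each list was tested with a two-sided Fisher's exact test of risen against fallen members, list against other entries of the table, with Benjamini-Hochberg adjustment over 102 tests.

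Named genes were, per table and among standard symbols, the 5 highest and 5 lowest fold changes, up to 2 highest and 2 lowest members of each list, and the whole panel; between days or species, the 5 highest and 5 lowest differences; and up to 6 genes with opposite directions. Exceptions, named after their values were seen, were Negr1, the brown fat markers, loci without a symbol and members of gene families. Panel genes listed numbered 21 on mouse day 2 (17 risen, 4 fallen), 22 on mouse day 5 (18 risen, 4 fallen), 16 on Acomys day 2 (16 risen, 0 fallen) and 19 on Acomys day 5 (17 risen, 2 fallen).

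Species were matched by symbol. The error of a fold change was rebuilt as its size divided by the z value of its p, where p is the FDR times its rank over 10000, an assumed number of tests, since the tables hold no unadjusted p. The difference between species was tested by a two-sided normal approximation with Benjamini-Hochberg adjustment over the symbols listed in both. The plan had named the authors' p-value; this replacement was made after simulated data showed that the FDR in its place called too few genes. The medians of lists were placed among 10000 random lists of the same size. For differences between days these were drawn from the other entries of either direction, without matching on mean expression. Shares have exact Clopper-Pearson 95% intervals, which cover counting error over genes only.

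The list direction test and the test of the species difference were tested on simulated data, the others were not. Random lists of 20 genes were called in 3.7%, 3.6%, 4.1% and 3.7% of cases in the tables of mouse day 2, mouse day 5, Acomys day 2 and Acomys day 5. For the species difference, 15000 genes were simulated with 200 changed: an added difference of 4 was called for 77.5% of changed genes listed in both on day 2 and 64.6% on day 5, and one of 2 for 0% and 1.12%. The median rebuilt error at logCPM above 4 was 0.33 and 0.32 in mouse and 0.44 and 0.48 in Acomys on days 2 and 5. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The alternatives were a stricter FDR, a minimum fold change, a floor on mean expression, standard symbols only, other matching of symbols and other rebuilt p-values. Leaving out libraries, other splits of the samples, batches and depth per library were not analysed here, as they need values per library. Some genes that the rule for named genes takes are not reported here.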

Results

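Kidney RNA was sequenced from adult male C57BL/6 mice, a standard laboratory strain, and from spiny mice (Acomys cahirinus), a rodent studied for its capacity to regenerate tissue. In each species 3 libraries came from sham operated animals, 3 from day 2 and 3 from day 5 of unilateral ureteral obstruction, in which the left ureter is closed, urine backs up and the kidney is injured. That made 18 libraries. Animals were 7 to 14 weeks old in the mouse sham group, 10.1 weeks on mouse day 2 and 10.1 to 14 weeks on mouse day 5, and the Acomys groups spanned 9.9 to 14.3 weeks in sham, 10.3 to 14.3 weeks on day 2 and 9.9 to 10.4 weeks on day 5. The values came from 4 tables of the authors' own comparisons, each of an obstructed group with the sham group of its species, and they hold only genes at a false discovery rate (FDR) under 0.05. Read totals per library are not given in the sources used here, so depth is unknown. A gene that was not listed may have been unchanged, too variable to pass or never tested. All fold changes are on the log2 scale that edgeR uses, a base the tables themselves do not state. The authors' FDRs, and the tests of the species difference rebuilt from them, rest on the spread between these libraries. The Fisher's exact, binomial and permutation tests count genes, which are not independent, and measure no spread between animals.

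On day 2 the mouse kidney showed 3915 changed genes, of which 2282 rose (58.3%) and 1633 fell. The first question was which kidney programmes had moved at this early time. Transcripts of tubule injury stood among the steepest rises: in the authors' deposited table Havcr1, the injury marker KIM-1 of the proximal tubule, rose by 8.60 (FDR 1.9e-08), Lcn2, the iron-binding lipocalin NGAL, by 7.29 (FDR 1.2e-07) and Spp1, osteopontin, by 5.41 (FDR 3.5e-09). Among standard symbols the steepest rise in the authors' deposited table was the acute-phase protein gene Saa1 at 9.51 (FDR 2.1e-05), followed by Sprr2f at 9.21, Il1f6 at 8.86 and Sprr2g at 8.74. At the other end, among standard symbols, the authors' deposited table held Pvalb, a calcium-binding protein of the distal convoluted tubule, at -8.54 (FDR 9.8e-08), Ces1g at -6.14, the growth factor gene Egf at -5.78 (FDR 2.8e-06), Cyp2d12 at -5.59 and Ucp1 at -5.56.

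All 20 tubule injury genes were listed and all 20 rose (median 3.22, adjusted p = 0.000167). Here and for the lists that follow, p is from a two-sided Fisher's exact test of risen against fallen members, set against the other genes of the same table and adjusted over 102 tests. Among them the authors' deposited table gave Krt20 at 5.88, the transcription factor Sox9 at 5.78 and Clu at 3.99. The proximal tubule list moved the other way, with 22 of 28 members fallen, 1 risen and 5 not listed (median -1.72, adjusted p = 6.41e-07). In the authors' deposited table Slc7a13 (-4.27), the organic anion transporter genes Slc22a7 (-4.11) and Slc22a8 (-3.15), the phosphate transporter gene Slc34a1 (-2.21) and the endocytic receptor gene Lrp2 (-1.59) fell, while the sulfate transporter gene Slc13a1 rose by 1.34. Of the loop, distal tubule and collecting duct genes 19 fell, 1 rose and 8 were not listed (median -1.65, adjusted p = 5.45e-06). Per the authors' deposited table Kcnj1, the potassium channel ROMK, fell by 1.91, Kl by 1.84 and the calcium channel gene Trpv5 rose by 1.90. Umod, which encodes uromodulin of the thick ascending limb, was not listed in mouse on this day.

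Matrix genes rose on day 2, 24 of 35 with 11 not listed and 0 fallen (median 2.03, adjusted p = 1.94e-05). The fibrillar collagen genes Col1a1 (3.76, FDR 1.2e-06) and Col3a1 (3.60, FDR 1.2e-06) and the fibronectin gene Fn1 (2.63) were among them in the authors' deposited table. All 16 listed myofibroblast and TGF-beta genes rose (median 2.03, adjusted p = 0.000854), with Tgfb1 at 2.04 and Acta2, smooth muscle actin, at 2.03 in the authors' deposited table. Of the matrix degradation genes 15 rose and 1 fell (median 2.55, adjusted p = 0.0120). The authors' deposited table held the protease gene Mmp7 at 7.62, the inhibitor gene Timp1 at 6.78 and Mmp13 at -1.97. All 10 listed collagen processing genes rose (median 1.63, adjusted p = 0.0218), including the crosslinking enzyme gene Lox at 2.69 in the authors' deposited table. That call ended at FDR under 0.01 (adjusted p = 0.0723), with a minimum change of 1 (adjusted p = 0.0743) and against standard gene symbols alone (adjusted p = 0.0537).

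Immune genes rose as well. The macrophage and monocyte list had 25 rises and 1 fall (median 2.26, adjusted p = 0.000139). Arg1 rose by 5.16, Trem2 by 4.05 and Cd68 by 2.88 in the authors' deposited table, and the efferocytosis receptor gene Mertk fell by 1.26. Cytokine and chemokine genes gave 27 rises and 1 fall (median 2.98, adjusted p = 4.97e-05). The authors' deposited table placed the neutrophil-attracting chemokine genes Cxcl5 (6.62), Cxcl2 (6.34) and Cxcl1 (6.06) high, the monocyte chemokine gene Ccl2 at 4.12 and Cxcl12 at -2.02. Complement genes rose 13 to 1 (median 2.18, adjusted p = 0.0341, but 0.0699 against standard gene symbols alone), with C3 at 6.35, Hc at 4.58 and the complement inhibitor gene Cd55 at -1.005 in the authors' deposited table. All 12 listed interferon response genes rose (median 1.36, adjusted p = 0.00730). The 5 listed neutrophil genes and the 5 listed T and NK cell genes also rose, without passing the list test (adjusted p = 0.177 for each).

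Cell cycle genes rose in 37 of 40 cases with 3 not listed (median 2.85, adjusted p = 5.21e-08), among them the mitotic kinase gene Aurkb (3.88), Ccne1 (3.77) and the proliferation marker gene Mki67 (3.43, FDR 1.3e-06) in the authors' deposited table. All 18 listed immediate early genes rose (median 2.55, adjusted p = 0.000507), led in the authors' deposited table by the AP-1 genes Fosl1 at 7.89 and Atf3 at 5.33. The metabolic lists fell: 21 fatty acid oxidation genes (median -1.45, adjusted p = 1.67e-07) and 21 mitochondrial respiration genes (median -0.91, adjusted p = 1.67e-07), with 0 rises in either. In the authors' deposited table Acsm2 fell by 2.49 and Ehhadh, a peroxisomal oxidation enzyme gene, by 1.92, while the respiratory chain genes Ndufs1 and Sdha fell by 1.24 and 1.17. With a minimum change of 1 only 2 respiration genes were left and that call ended (adjusted p = 0.310). Beside these lists, 5 of 11 brown fat markers also fell in mouse on day 2, including Cidea at -4.05 and Cox7a1 at -2.24 in the authors' deposited table. The marker set was chosen after the fall of Ucp1 was seen, and Ucp1 itself counts among the 5. Mean expression was low for Ucp1, Cidea and Cox8b (logCPM 1.10, 0.46 and -0.32 in the authors' deposited table). The fat genes Adipoq, Plin1 and Lep of the set were not listed.

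The other lists did not pass the test on mouse day 2. Arrest and senescence genes rose 8 to 0 (adjusted p = 0.0710), with Gdf15 at 3.30 and the cell cycle inhibitor gene Cdkn1a at 2.497 in the authors' deposited table. Oxidative defence genes rose 7 to 4 and held Gpx2 at 6.18 beside the catalase gene Cat at -1.34 in the authors' deposited table. The mean expression (logCPM) of Gpx2 was only -2.51, against 9.16 for Cat. Risen and fallen members numbered 6 and 3 for the Wnt pathway, 1 and 3 for kidney development, 5 and 2 for glycolysis, 3 and 3 for urothelium, 0 and 2 for adipocytes, 0 and 1 for adrenal tissue, 1 and 1 for erythroid cells and 0 and 1 for endothelium, with no podocyte or B and plasma cell gene listed.

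**Figure D1:**
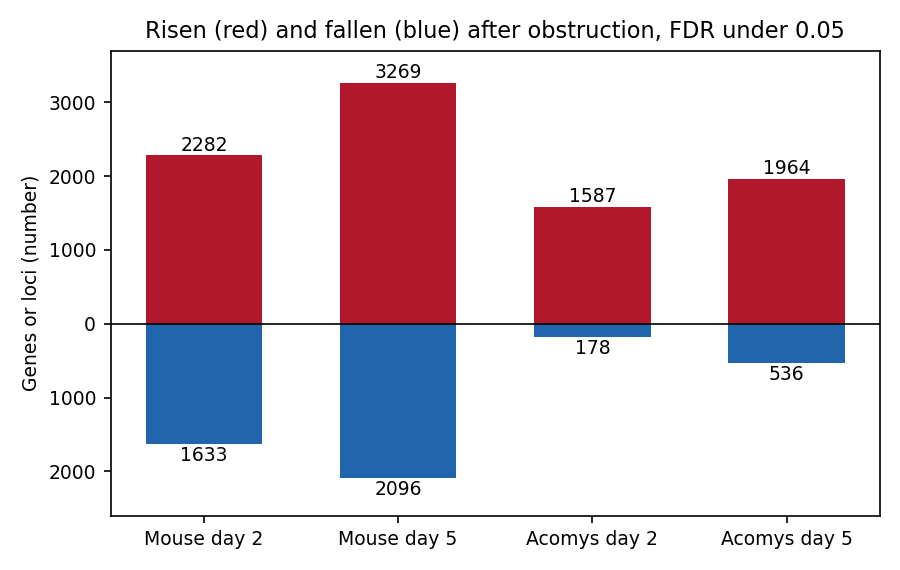
Bars give the number of genes (mouse) or loci (Acomys) that rose (red, above 0) or fell (blue, below 0) against the sham group of the same species at FDR under 0.05, in the authors' deposited tables. Falls numbered 1633 and 2096 in mouse and 178 and 536 in Acomys on days 2 and 5.

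By day 5 the mouse kidney listed 5365 genes, 3269 risen (60.9%) and 2096 fallen. This comparison asked which programmes were changed once obstruction had lasted longer. Among standard symbols the steepest rises in the authors' deposited table were the muscle gene Xirp2 (10.67, FDR 3.7e-05), Mmp7 (9.33, FDR 7.6e-07), Kcnh8 (8.91, logCPM -0.68), Arhgap36 (8.61) and Havcr1 (8.19, FDR 1.9e-08). The lowest values among those symbols were Pvalb at -10.82 (FDR 3.9e-08), Lrrc52 at -5.96 (logCPM -0.78), Ucp1 at -5.84, Ces1g at -5.37 and Egf at -4.98 in the authors' deposited table.

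Matrix genes rose in 34 of 35 cases, with 0 falls (median 2.57, adjusted p = 8.14e-07). Per the authors' deposited table Ltbp2, which binds elastic fibres, rose by 5.20, Col1a1 by 4.23 (FDR 3.3e-07), Col3a1 by 4.14 and Lum, the collagen-binding lumican, by 2.46. The 21 listed myofibroblast and TGF-beta genes rose without exception (median 2.38, adjusted p = 0.000225), including Thy1 at 4.19, Tgfb1 at 2.64 and Acta2 at 2.13 in the authors' deposited table. Matrix degradation genes rose 21 to 1 (median 3.07, adjusted p = 0.00233), the fall being Timp3 at -1.06 in the authors' deposited table. Collagen processing genes rose 11 to 1 (adjusted p = 0.0926, and 0.0496 at FDR under 0.01), with Lox at 4.26 in the authors' deposited table.

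On day 5 the macrophage and monocyte list gave 26 rises and 1 fall (median 3.56, adjusted p = 0.000189). Adgre1, the macrophage antigen F4/80, stood at 3.61 (FDR 1.1e-07) and Trem2 at 4.96 in the authors' deposited table. All 14 listed T and NK cell genes rose (median 2.01, adjusted p = 0.00539), among them Klrd1 at 2.98, Lck at 2.58 and Cd3e at 2.57 in the authors' deposited table. Cytokine and chemokine genes rose 32 to 0 (median 3.25, adjusted p = 1.31e-06), with Tnfsf11 at 6.56 and Ccl2 at 5.63 in the authors' deposited table. Interferon response genes rose 23 to 0 (median 1.88, adjusted p = 8.80e-05) and complement genes 17 to 1 (median 3.08, adjusted p = 0.00919). The 6 listed neutrophil genes (adjusted p = 0.187) and 4 listed B and plasma cell genes (adjusted p = 0.293) rose without passing the list test, Jchain standing at 4.03 in the authors' deposited table.

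Tubule injury genes rose 19 to 0 (median 3.16, adjusted p = 0.000698). All 27 listed proximal tubule genes fell (median -2.05, adjusted p = 2.92e-10), with Slc22a8 at -3.54, Slc34a1 at -2.17 and Lrp2 at -2.05 in the authors' deposited table. The loop, distal tubule and collecting duct list held 19 falls and 1 rise (median -1.74, adjusted p = 1.79e-06), and Kl fell by 2.15 in the authors' deposited table. Fatty acid oxidation genes fell 30 to 0 (median -1.53, adjusted p = 2.55e-11), including Acsm2 at -2.30 and Ehhadh at -1.79 in the authors' deposited table. Mitochondrial respiration genes fell 35 to 0 (median -1.12, adjusted p = 4.43e-13). Of the 11 brown fat markers 4 fell on day 5, Ucp1 again among them, with Cidea down by 4.46 and Cox7a1 by 1.83 in the authors' deposited table. Another of the 11, Dio2, rose by 3.32. Cell cycle genes rose 36 to 0 (median 2.34, adjusted p = 3.01e-07) and immediate early genes 16 to 0 (median 2.36, adjusted p = 0.00190).

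The Wnt pathway list had 11 rises and 1 fall on day 5 (adjusted p = 0.0926), with Nkd2 at 4.23, Wnt7a at 4.21 and the inhibitor gene Notum at -1.68 in the authors' deposited table. Oxidative defence genes fell 9 to 4 (adjusted p = 0.107, and 0.00878 at FDR under 0.01), where the superoxide dismutase gene Sod2 stood at -1.61 and Gpx2 at 5.23 (FDR 0.048, logCPM -2.51) in the authors' deposited table. Risen and fallen members were 9 and 1 for arrest and senescence, 6 and 5 for kidney development, 5 and 3 for glycolysis, 4 and 0 for urothelium, 2 and 1 for podocytes, 1 and 0 for endothelium, 0 and 2 for adipocytes, 1 and 1 for adrenal tissue and 1 and 1 for erythroid cells, and none of these passed the test.

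Between day 2 and day 5 the mouse response grew for matrix, macrophage and interferon genes and receded for cell cycle genes. The median day 5 minus day 2 difference was 0.81 for matrix genes, with 24 of 24 members listed on both days higher, 1.21 for macrophage genes (22 of 26 higher) and 0.69 for interferon genes (12 of 12 higher). Cell cycle genes were lower in 36 of 36 cases (median -0.58). Among 10000 random lists of the same size, not matched on mean expression, these medians stood at percentiles 100, 100, 99.8 and 0. That describes these libraries and is not a test across animals. Siglec1, a macrophage sialic acid receptor gene, went from 1.71 to 5.21, the elastic fibre gene Fbn2 from 2.88 to 5.73 and Adgre1 from 1.27 to 3.61 in the authors' deposited tables, while Saa1 went from 9.51 to 5.39 and the fibrinogen chain genes Fgb from 6.61 to 3.63 and Fga from 4.97 to 2.53. Mitochondrial respiration genes were lower on day 5 in 21 of 21 cases (median -0.28, percentile 0.12) and proximal tubule genes in 17 of 22 (median -0.33, percentile 0.02).

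Of the day 2 genes in mouse, 3369 (86.1%) were also listed on day 5, with 2006 risen and 1362 fallen on both days and 1, Negr1, in opposite directions (chosen after its values were seen). Across these genes, which are not independent replicates, fold changes had Pearson r = 0.963 and Spearman rho = 0.945, and a covariance of 4.79. Both days were set against the same 3 sham libraries. Simulated unchanged groups against shared controls gave r = 0.507 over all 20000 genes. Only 177 of these were called on both days, at an unadjusted p under 0.05, and they had r = 0.970 with 99.4% the same sign. A high r among genes called on both days is therefore no evidence of agreement by itself. The simulated cut was looser than the FDR used here and called far fewer genes than the 3369 listed. The simulation thus does not account for the number of shared genes. From the rebuilt errors, shared controls would add a covariance of 0.157. Independent lists of these sizes would share 373 rises and 171 falls among an assumed 20000 tested genes, and 746 and 342 among 10000, the number assumed for the rebuilt p-values. The sham libraries could not be split without values per library, so part of the excess may come from the shared controls.

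**Figure D2:**
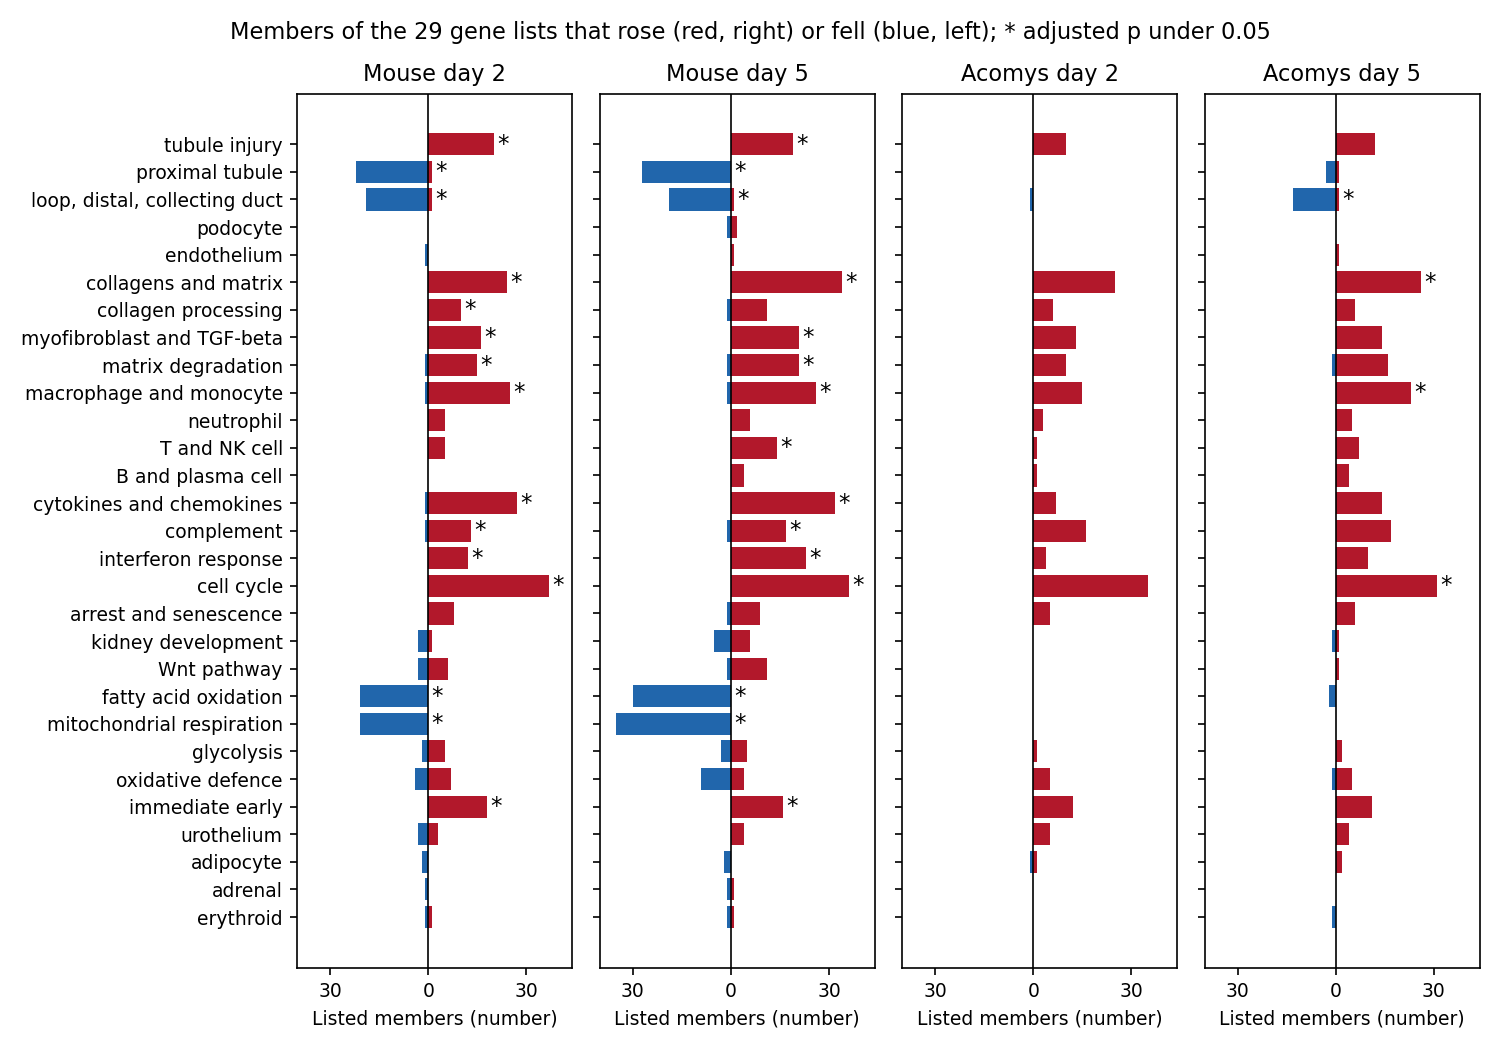
Bars give how many members of each of the 29 gene lists rose (red, right) or fell (blue, left) at FDR under 0.05 in each of the 4 comparisons, and a star marks an adjusted p under 0.05 in the two-sided Fisher's exact test of direction. The star count is 15 on both mouse days, 0 on Acomys day 2 and 4 on Acomys day 5.

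In Acomys 1765 loci were listed on day 2, of which 1587 rose (89.9%) and 178 fell. The question was how the Acomys kidney responded at the same early time. In the authors' deposited table Lcn2 rose by 6.88 (FDR 1.2e-05), Col1a1 by 4.54 (FDR 6.8e-06), Mki67 by 4.27 (FDR 7.2e-05) and Timp1 by 4.20 (FDR 1.3e-05). Loci without a standard symbol reached 10.61 and -8.65 in the authors' deposited table. Among standard symbols the steepest rises in the authors' deposited table were Acrv1 (7.39), the homeobox gene Gbx2 (7.24), Serpina1b, an alpha-1-antitrypsin gene (7.24, FDR 0.00032), and the interleukin-1 decoy receptor gene Il1r2 (7.15), of which Acrv1, Gbx2 and Il1r2 had a mean expression (logCPM) below 0. Cacng5 (-5.36, logCPM -2.24), Bpifc (-5.29), Emc9 (-4.21), Vmp1 (-4.07) and Aldh1a7 (-3.69) lay lowest among standard symbols in the authors' deposited table.

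Cell cycle genes rose 35 to 0 with the highest median of the large lists (3.56), including Nusap1 at 4.74, Ccna2 at 4.53 and Ccnb2 at 4.25 in the authors' deposited table. Matrix genes rose 25 to 0 (median 2.20), with Col3a1 at 3.74, Lum at 3.22 and Fn1 at 3.18 in the authors' deposited table. The myofibroblast and TGF-beta list gave 13 rises (median 2.17), among them Tagln at 3.31, Acta2 at 2.75, Ccn2, connective tissue growth factor, at 2.17 and Tgfb1 at 1.41 in the authors' deposited table. Rises alone were also listed for macrophage genes (15, median 2.16), complement (16, median 1.96), immediate early genes (12, median 2.16), tubule injury genes (10, median 2.40), matrix degradation (10), cytokines and chemokines (7), collagen processing (6), oxidative defence (5), arrest and senescence (5), urothelium (5), interferon response (4), neutrophils (3), and 1 each for T and NK cells, B and plasma cells and glycolysis. With loci added that carry a protein name but no matching symbol, an alternative chosen after seeing the data, tubule injury gave 15 risen loci, cytokines and chemokines 12 and T and NK cells 2. A gene with several loci, such as Spp1, counts more than once there. No list passed the test. The authors' deposited table held the metallothionein gene Mt2 at 6.04, the lactoferrin gene Ltf at 6.22 and Csf1r, the macrophage growth factor receptor, at 2.13.

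No list passed the direction test on Acomys day 2, where 89.9% of all listed loci rose. The cell cycle list alone, 1 of those tested, had an unadjusted p under 0.05 (Fisher's exact p = 0.0431, adjusted p = 0.107). Matrix genes gave an adjusted p of 0.301. In this table a list of 20 genes that all rose would reach an exact p of only 0.253. No member was listed from the proximal tubule, fatty acid oxidation, mitochondrial respiration, Wnt, kidney development, podocyte, endothelium, adrenal and erythroid lists. At logCPM above 6 the smallest fall listed on this day was 1.47 in Acomys, against 0.74 in mouse. Smaller falls of such genes may therefore have gone unlisted. From the loop, distal tubule and collecting duct list 1 gene fell, the prostaglandin receptor gene Ptger3 at -1.64 in the authors' deposited table, and adipocyte genes gave 1 rise and 1 fall. Havcr1, Spp1, Egf, Kl, Lrp2, Slc34a1, Adgre1 and Umod were not listed under these symbols. Loci with the protein names of Havcr1 and Spp1 were listed in the authors' deposited table, the highest of each at 6.91 and 2.51, which was looked up after the data were seen. At FDR under 0.01 the count was 963 and among standard gene symbols 1104, with 96.3% risen in each.

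On day 5 Acomys listed 2500 loci, 1964 risen (78.6%) and 536 fallen. This comparison followed the response to the later time. Loci without a standard symbol reached 10.52 and -8.86 in the authors' deposited table. Among standard symbols there, the NADPH oxidase gene Nox1 rose by 7.92 (FDR 0.002, logCPM below 0), Serpina1b by 7.77, Serpina10 by 7.54 and Lcn2 by 7.17 (FDR 1.6e-05), and Acrv1 and Gbx2 stood highest at 8.08 and 7.99 in the authors' deposited table. Cacng5 (-7.36, logCPM -2.24), Bpifc (-5.64), Aldh1a7 (-4.98), Gpx6 (-4.77) and Vmp1 (-4.68) were lowest among standard symbols in the authors' deposited table.

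Matrix genes rose 26 to 0 in Acomys on day 5 (median 2.38, adjusted p = 0.01004), with Col1a1 at 4.71 (FDR 9.2e-06), Lum at 4.43, Col3a1 at 4.37 and Fn1 at 3.79 in the authors' deposited table. Macrophage and monocyte genes rose 23 to 0 (median 2.69, adjusted p = 0.0249), including the fungal receptor gene Clec7a at 5.11, Clec4d at 4.64 and Csf1r at 2.81 in the authors' deposited table. Cell cycle genes rose 31 to 0 (median 2.16, adjusted p = 0.00284). These 3 calls ended at FDR under 0.01 (adjusted p = 0.378, 0.762 and 0.378) and against standard gene symbols alone (0.170, 0.240 and 0.0749). Every listed member still rose in both settings, where 91.3% and 87.7% of all entries rose. A list of rises alone could do no better there at those sizes. The loop, distal tubule and collecting duct list fell 13 to 1 (median -2.39, adjusted p = 2.96e-07). Egf stood at -3.80 (FDR 0.012), Kcnj1 at -3.61 (FDR 0.008) and Umod at -2.29 (FDR 0.0098) in the authors' deposited table, against a rise of Trpv5 by 2.65.

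Other lists fell short of the test on Acomys day 5. With 78.6% of loci risen, even 14 rises and 0 falls gave an unadjusted Fisher's exact p of only 0.0505. Lists of that size or smaller with rises alone could therefore not pass. Cytokines and chemokines rose 14 to 0 (median 3.38, adjusted p = 0.117) and complement genes 17 to 0 (median 2.60, adjusted p = 0.0909), with Ccl3 at 5.89 and C3 at 4.50 in the authors' deposited table. Once loci that carry a protein name but no matching symbol were added, an alternative chosen after seeing the data, these became 22 to 0 (adjusted p = 0.0227) and 20 to 0 (adjusted p = 0.0344). Those are counts of loci, so a gene with several loci, such as C3, counts more than once. Proximal tubule genes fell 3 to 1 (median -1.18, adjusted p = 0.0909) and fatty acid oxidation genes 2 to 0 (adjusted p = 0.111), Acsm3 at -2.34 and Hadh at -1.38 in the authors' deposited table. Against standard gene symbols alone these had an adjusted p of 0.0236 and 0.0498. Rises and falls were 14 and 0 for myofibroblast and TGF-beta genes (adjusted p = 0.117), 12 and 0 for tubule injury (adjusted p = 0.177), 16 and 1 for matrix degradation, 11 and 0 for immediate early genes, 10 and 0 for interferon response, 7 and 0 for T and NK cells, 6 and 0 for collagen processing, 6 and 0 for arrest and senescence, 5 and 1 for oxidative defence, 5 and 0 for neutrophils, 4 and 0 for B and plasma cells and 4 and 0 for urothelium. The remaining lists gave 2 and 0 for glycolysis, 2 and 0 for adipocytes, 1 and 1 for kidney development, 1 and 0 for the Wnt pathway, 1 and 0 for endothelium and 0 and 1 for erythroid cells, with no mitochondrial respiration, podocyte or adrenal gene listed. At FDR under 0.01 the day 5 count was 1189 (91.3% risen), and among standard gene symbols 1387 (87.7% risen).

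From day 2 to day 5 in Acomys, cell cycle genes receded, and macrophage, complement and matrix degradation genes grew. All 31 cell cycle genes listed on both days were lower on day 5 (median difference -1.51), with Ccnb2 going from 4.25 to 2.11, Cdc20 from 4.02 to 1.98 and Mki67 from 4.27 to 2.55 in the authors' deposited tables. Macrophage genes were higher in 14 of 15 cases (median 0.62), complement genes in 15 of 16 (median 0.61), matrix degradation genes in 10 of 10 (median 0.53) and matrix genes in 22 of 25 (median 0.34). The gelatinase gene Mmp9 went from 3.02 to 5.71 and Gzmf, a granzyme gene, from 5.50 to 7.20 in the authors' deposited tables. Among 10000 random lists these medians lay at percentiles 0, 99.9, 99.9, 98.7 and 98.0. For the 31 cell cycle genes listed in all 4 tables the median difference between days was -0.55 in mouse and -1.51 in Acomys, and 30 of 31 had the lower difference in Acomys (median -0.90 between species, percentile 0 of random lists, with no test across animals). Their median fold change was 2.86 in mouse and 3.59 in Acomys on day 2, and 2.37 and 2.16 on day 5.

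Of the day 2 loci in Acomys, 1319 (74.7%) were also listed on day 5, with 1220 risen on both days, 99 fallen on both and 0 in opposite directions. At FDR under 0.01 the shared number was 687. Across these loci fold changes had Pearson r = 0.946, Spearman rho = 0.864 and a covariance of 4.51, against a covariance of 0.411 that the shared sham libraries would add, from the rebuilt errors. Here too r by itself is no evidence, since simulated unchanged groups gave 0.970 over genes called on both days, 99.4% with the same sign. Those were 177 of 20000 genes at an unadjusted p under 0.05, so the simulation does not account for the number of shared loci. Independent lists would share 156 rises and 4.77 falls among 20000 tested genes, or 312 and 9.54 among 10000, and part of the excess may again come from the shared controls.

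**Figure D3:**
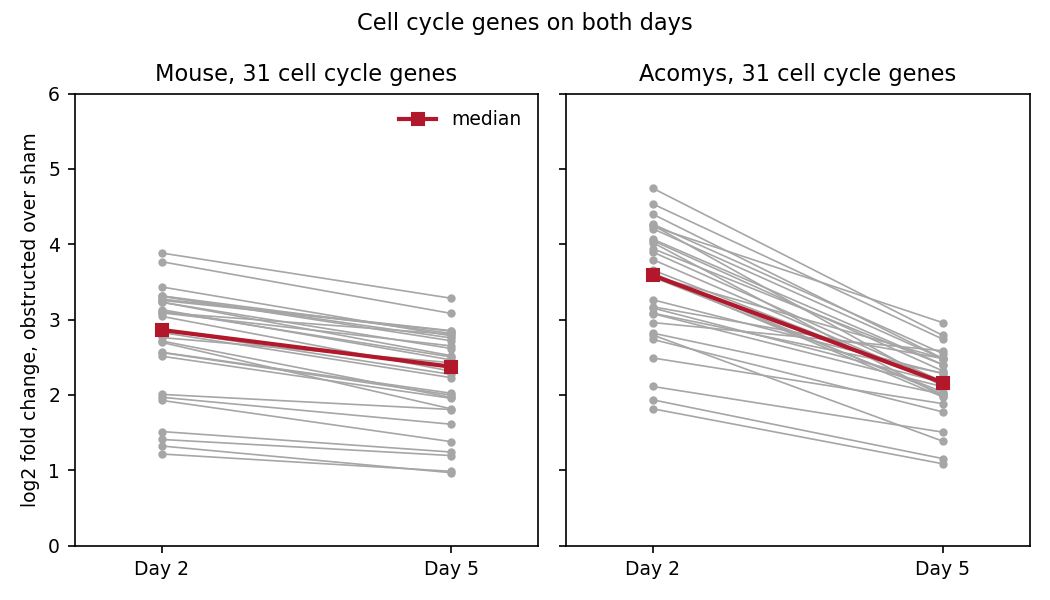
Each grey line joins the log2 fold changes (obstructed over sham, from the authors' deposited tables) of 1 cell cycle gene on days 2 and 5, for the 31 genes listed in all 4 comparisons, and red squares mark the median. The median went from 2.86 to 2.37 in mouse and from 3.59 to 2.16 in Acomys.

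Set side by side on day 2, the rises of matrix, cell cycle and complement genes in mouse were shared with Acomys above the level of other mouse rises. Few mouse falls of any kind were listed in Acomys, among them 0 of 22 proximal tubule genes against 1.06% of other mouse falls (Fisher's exact p = 1, two-sided). This comparison addresses how the response of Acomys differs from that of the laboratory mouse. Recovery was not measured in these data. The 2 species shared 729 listed symbols, of which 685 rose in both, 17 fell in both and 27 went in opposite directions, so 96.3% had the same direction. Independent directions with these symbols' own shares of rises would give 91.9% (two-sided Fisher's exact p = 1.45e-20, chosen after the data were seen, over genes that are not independent). The planned exact binomial test took 57.7% from the shares of the whole tables (p = 2.84e-129), which makes the excess look larger than it is among the shared symbols. Of 37 mouse cell cycle genes that rose, 34 (91.9%) also rose in Acomys, against 29% of other mouse rises (two-sided Fisher's exact test, adjusted p = 1.45e-13 over 53 tests chosen after the data were seen). The same held for 12 of 13 complement genes (adjusted p = 3.13e-05), 17 of 24 matrix genes (adjusted p = 0.000237) and 11 of 18 immediate early genes (adjusted p = 0.0306), the last of which ended at FDR under 0.01 (adjusted p = 0.152) and at logCPM above 4 (adjusted p = 0.149). Tubule injury genes were shared in 10 of 20 cases, which did not pass the test (adjusted p = 0.198). That count leaves out Havcr1 and Spp1, since the Acomys loci with their protein names, the highest at 6.91 and 2.51 in the authors' deposited table, carry no matching symbol. Of mouse genes that fell by at least 2 with logCPM above 4, 6 of 131 were listed as fallen in Acomys, against 128 of 223 that rose (Fisher's exact p = 1.15e-26, two-sided, chosen after the data were seen). The fold change of cell cycle genes was higher in Acomys in 28 of 34 cases (median difference 0.77, percentile 99.99 of 10000 random lists). That of immediate early genes was lower in Acomys in 8 of 11 cases (median difference -0.55, percentile 0.78), and of 7 shared cytokine genes 4 were lower and 3 higher (median difference -1.07, percentile 0.13). In each of these lists 0 members passed the test of the difference, and a percentile among random lists is not a test across animals. Those random lists were not matched on mouse fold change.

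Fold changes of the shared symbols on day 2 had Pearson r = 0.551 and Spearman rho = 0.581 across genes, and 37 genes differed between species after adjustment, 29 higher in Acomys and 8 higher in mouse. Of these 37, 27 had opposite directions, where listing in both species all but ensures a pass. Among the differing genes, Saa1 stood at 9.51 in mouse and 1.91 in Acomys in the authors' deposited tables, Il1rn, the interleukin-1 receptor antagonist gene, at 6.97 and 1.69, Mt2 at 2.07 and 6.04, and Rarres2, the chemerin gene, at -2.06 and 2.93. Their Acomys minus mouse differences were -7.60 (SE 2.03, adjusted p = 0.00491), -5.28 (SE 1.38, adjusted p = 0.00375), 3.97 (SE 1.04, adjusted p = 0.00391) and 4.99 (SE 0.78, adjusted p = 4.65e-08), by a two-sided normal approximation with p rebuilt from the edgeR FDR. The Saa1 value rests on the locus with that symbol, and a second locus with the same protein name stood at 4.02 in the authors' deposited table. Fosl1 was at 7.89 and 3.41 in the authors' deposited tables, a difference of -4.47 that missed the threshold (adjusted p = 0.157). At FDR under 0.01 the shared symbols numbered 452 and the differing genes 16. Il1rn, with an Acomys FDR of 0.039, was not among the symbols kept. In simulations a true difference of 4 was called for 77.5% of genes and one of 2 for 0%.

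On day 5 the overlap was wider and took in the falls of distal tubule genes. Both species listed 1011 symbols, with 892 risen in both, 84 fallen in both and 35 opposite, or 96.5% in the same direction against 81.9% from these symbols' own shares of rises (two-sided Fisher's exact p = 8.88e-88). The planned exact binomial test against 58.3%, from the whole tables, gave p = 5.11e-178. Of 19 loop, distal tubule and collecting duct genes that fell in mouse, 11 (57.9%) also fell in Acomys, against 3.51% of other mouse falls (two-sided Fisher's exact test, adjusted p = 2.28e-10). Sharing above that of other mouse rises was also found for cell cycle (31 of 36, adjusted p = 5.01e-12), matrix (25 of 34, adjusted p = 2.38e-07), macrophage (21 of 26, adjusted p = 2.38e-07), complement (15 of 17, adjusted p = 2.13e-06), matrix degradation (16 of 21, adjusted p = 3.07e-05), myofibroblast and TGF-beta (13 of 21, adjusted p = 0.00474), tubule injury (12 of 19, adjusted p = 0.00533) and immediate early genes (10 of 16, adjusted p = 0.0145). The immediate early call ended at FDR under 0.01 (adjusted p = 1) and at logCPM above 4 (adjusted p = 0.332), and the myofibroblast call at logCPM above 4 (adjusted p = 0.173). Fatty acid oxidation falls were shared in 2 of 30 cases (adjusted p = 0.501), mitochondrial respiration falls in 0 of 35 (adjusted p = 0.571) and proximal tubule falls in 3 of 27 (adjusted p = 0.210), none of which passed the test against other mouse falls. At logCPM above 6 the smallest fall listed on day 5 was 1.14 in Acomys and 0.72 in mouse. The mouse median was -1.12 for respiration and -1.53 for fatty acid oxidation. Absence from the Acomys falls thus does not show that these genes were spared.

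Among shared matrix genes the Acomys minus mouse difference on day 5 had a median of -0.07 (percentile 67.3 of random lists), and Col1a1 stood at 4.23 in mouse and 4.71 in Acomys in the authors' deposited tables. Fold changes of macrophage genes listed in both species were lower in Acomys in 18 of 21 cases (median -0.97, percentile 0.03), such as Adgre1 at 3.61 and 1.79 in the authors' deposited tables. The 3 higher ones included Clec7a (3.56 in mouse, 5.11 in Acomys) and Clec4d (3.60 and 4.64). Csf1r, at 2.81 in Acomys, was not listed in mouse and does not enter. The random lists were not matched on mouse fold change, whose median was 3.57 here against 2.33 for symbols risen in both. The percentile may partly reflect that. Those of T and NK cell genes were higher in 5 of 7 cases (median 0.87, percentile 98.9). Of the matrix, macrophage and T and NK cell genes, 0 passed the test of the difference. The 52 genes that differed after adjustment included 33 higher in Acomys and 19 higher in mouse, and fold changes had r = 0.681 and rho = 0.532 across genes. Of these 52, 35 had opposite directions, where listing in both species all but ensures a pass. Timd2, a ferritin receptor gene, was at 0.90 in mouse and 5.87 in Acomys, Serpina1b at 1.81 and 7.77, and Osr1, a kidney progenitor transcription factor gene, at -1.22 and 1.86 in the authors' deposited tables, with differences of 4.96 (SE 1.22, adjusted p = 0.00183), 5.96 (SE 1.79, adjusted p = 0.0184) and 3.09 (SE 0.80, adjusted p = 0.00342). The Timd2 value rests on the locus with that symbol. Further loci named TIMD2, without a symbol, stood at 6.72 and 7.45 and a locus named HAVR1 at 8.14 in the authors' deposited table. Mouse listed Serpina1c and Serpina1d apart from Serpina1b. How transcripts of the same gene family were told apart in Acomys is not known, so the Timd2 and Serpina1b differences are uncertain. At FDR under 0.01 the shared symbols numbered 591 and the differing genes 25. The planned test of risen against fallen members between species called 0 of 45 lists (two-sided Fisher's exact tests, 0 at an unadjusted p under 0.05). Many lists had no falls in either species, which fixes the p at 1, so this test does not show that the lists moved alike.

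**Figure D4:**
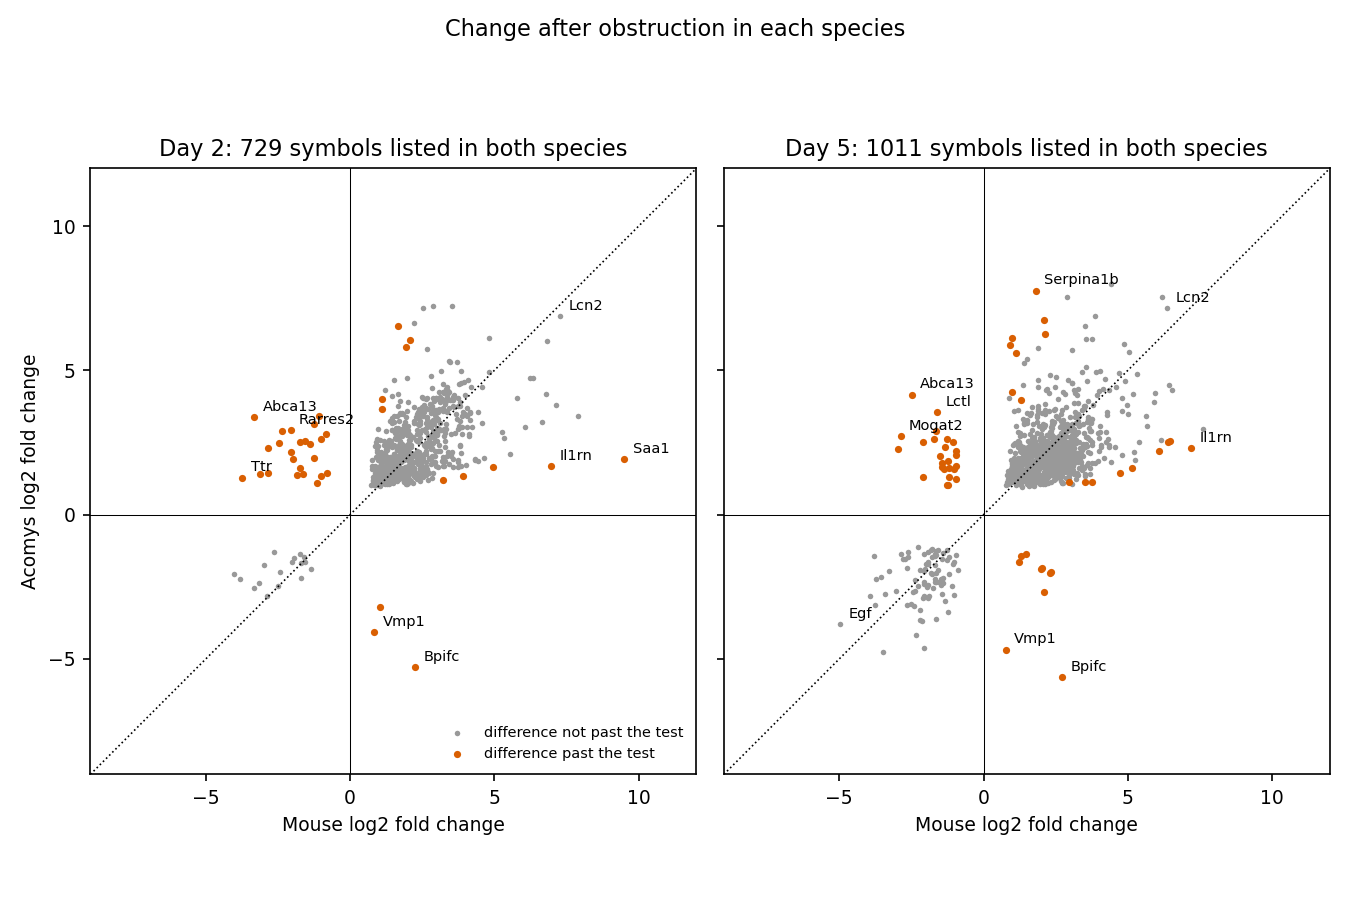
Each point is a symbol listed in both species, at its log2 fold change in mouse (horizontal) and Acomys (vertical) from the authors' deposited tables, on day 2 (left, 729 symbols) and day 5 (right, 1011 symbols), with equal values on the dotted line. Orange points, 37 and 52 of them, differed between species at an adjusted p under 0.05, and the empty bands near 0 arise because the tables hold only genes past the FDR threshold.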

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

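The tests of precision, of missing symbols, of scaling and of a shift of all risen genes, and the comparison of mouse falls with rises in Acomys, were chosen only after the results were seen, and the bars for scaling and for the shift were set anew after that. Every difference given here between species passed the test of the difference itself, or in the case of shares a two-sided Fisher's exact test. All 27 symbols with opposite directions on day 2 and all 35 on day 5 passed. Their listing in both species at FDR under 0.05 all but ensured this, so for them the pass adds no support beyond the listing.

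On day 2 the Acomys minus mouse difference of log2 fold change was below 0 for Saa1 (-7.60), Bpifc (-7.53), Il1rn (-5.28) and Vmp1 (-4.91). The Saa1 difference uses the Acomys locus with that symbol, at 1.91, while a second locus with the same protein name stood at 4.02 in the authors' deposited table. The difference was above 0 for Upk3a, a urothelial plaque gene (3.19), Mt2 (3.97), Cabp2 (4.24), Sbsn (4.88), Ccdc180 (4.96), Rarres2 (4.99), Ttr, the thyroid hormone carrier transthyretin (5.01), Mogat2 (5.15), Nsg2 (5.29) and Abca13 (6.69). On day 5 it was below 0 for Bpifc (-8.37), Vmp1 (-5.46), Il1rn (-4.90), Treml2 (-4.76) and Crtac1 (-4.31), and above 0 for Osr1 (3.09), Ccdc180 (4.33), Mt2 (4.48), Nsg2 (4.54), Itih2 (4.63), Timd2 (4.96), Sbsn (5.14), Lctl (5.18), Mogat2 (5.59), Serpina1b (5.96) and Abca13 (6.65). The Timd2 difference uses the Acomys locus with that symbol, while further loci named TIMD2 stood at 6.72 and 7.45 in the authors' deposited table. Serpina1b has close paralogues listed in mouse, so its difference is uncertain as well. Of all differing genes, 20 differed on both days.

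Some of these genes rose in one species and fell in the other, 27 on day 2 and 35 on day 5, with 14 on both days, 12 of which fell in mouse and rose in Acomys. A candidate explanation is that the Acomys locus is a fragment or another gene than its symbol says. Their mean expression differed more between species than that of genes with the same direction, by a median of 1.49 against 0.67 log2 units on day 2 (permutation p = 0.00019) and 2.08 against 0.77 on day 5 (permutation p = 1e-05, the smallest that 100000 permutations can give). A true difference between the species, which the design names, would also fit a difference in expression level and stays open as untested.

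Among mouse genes with a change of at least 2 and logCPM above 4, 6 of 131 falls (4.58%, interval 1.70 to 9.70) were listed on day 2 against 128 of 223 rises (57.4%, Fisher's exact p = 1.15e-26), and 23 of 149 falls (15.4%, interval 10.0 to 22.3) on day 5 against 219 of 327 rises (67.0%, Fisher's exact p = 6.74e-27). Lower precision by 1 factor for all genes was argued against as the whole cause: the stricter FDR in mouse that kept as many rises as Acomys listed kept 43 of 131 falls on day 2 (32.8%, interval 24.9 to 41.6) and, by a narrow margin over the upper bound of 22.26 for listed falls, 44 of 149 on day 5 (29.5%, interval 22.35 to 37.5). Crediting every fallen Acomys locus without a symbol above logCPM 2 to a mouse fall raised the share to 13.0% on day 2 (interval 7.74 to 19.96) and 44.97% on day 5 (interval 36.8 to 53.3), under the lower bounds for rises of 50.6% and 61.6%. Both measures replaced earlier ones after the results were seen, for precision because the earlier one only restated the pattern: for symbols, all fallen loci above logCPM 4, whatever their symbol, numbered 21 on day 2 against a bar of 65.5, and 102 on day 5 against a bar of 74.5, so on day 5 the earlier measure left missing or wrong symbols open. Open as well are precision and missing symbols together on day 5, where the credited share passes 29.5%, a scaling shift, since genes risen in both species differed both ways (medians 0.18 and -0.18, 95% of genes between -2.15 and 2.10 on day 2 and between -2.14 and 2.51 on day 5) and had to be listed in both, greater variability among the Acomys sham libraries in genes of the healthy tubule, which needs values per library, and a biological difference between the species, which was not tested.

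Cell cycle genes were lower on day 5 than on day 2 in Acomys by a median of -1.51. A shift of all risen genes between the days was argued against by the other 1189 genes risen on both days, whose median difference was 0.086 (95% of them between -1.49 and 1.21), and regression of high day 2 values by 10000 lists matched on day 2 fold change and logCPM, among which the cell cycle median lay at percentile 0 (regression test, random median -0.08, lowest -1.27). No biological explanation was tested, and the age range of the groups and differences among single libraries stay open.

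Loci without a symbol numbered 644 on day 2 and 1094 on day 5, and these, with loci whose symbol is not that of their protein name, hold signals that the comparisons by symbol do not use. The highest locus with the UniProt name HAVR1, the protein of Havcr1, rose by 6.91 on day 2 and 8.14 on day 5 in the authors' deposited tables, where its symbol is Gm4926. The highest locus named OSTP, osteopontin, rose by 2.51 and 1.74 in the authors' deposited tables, so the absence of Havcr1 and Spp1 from the Acomys symbols does not show that these genes stayed unchanged.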

How the results depend on the processing

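Among the alternatives, matching by Entrez ID, other rebuilt p-values, loci added by protein name, and all settings for shared lists, for the difference of cell cycle genes between days, for mouse changes listed in Acomys and for named genes were chosen after seeing the data. Over 23 results and 86 alternatives (60 planned, 26 added), 75 kept their direction and their side of the threshold or stayed within 1.5 times the count, 11 counts moved further and 0 reversed. Many of the 75 had little or no room to change. No symbol was repeated, so 1 row per symbol gave the same counts, and other matching between species returned the same numbers. A minimum change of 1 left 1758 and 2494 Acomys loci on days 2 and 5. List counts of 0 on Acomys day 2 and between species stayed at 0. The tally is thus no measure of robustness. A steady count can hide other members: against standard symbols alone, 3 lists were called on Acomys day 5, but only 1 of the main 4 was among them. At FDR under 0.01 the Acomys count went from 1765 to 963 on day 2 and from 2500 to 1189 on day 5, loci shared by the Acomys days from 1319 to 687, and symbols listed in both species from 729 to 452 and from 1011 to 591. Genes that differed between species went from 37 to 16 and from 52 to 25. The share of them with the same direction went from 27.0% to 43.75% and from 32.7% to 52%, and the cause was not tested. Called lists on Acomys day 5 went from 4 to 1 while falls in that table went from 536 to 104. The lost matrix, macrophage and cell cycle lists still held rises alone (25, 18 and 28). With 91.3% of entries risen, such lists could reach a Fisher's exact p of only 0.159, 0.394 and 0.165. They could therefore not pass at that FDR, whatever the genes did. With standard symbols only, Acomys counts went to 1104 and 1387, and matched by symbol the Acomys days shared 864, since loci without a symbol drop out. Genes that differed numbered 25 and 36 with the FDR used in place of p, of which 8% and 8.33% had the same direction in both species. With 30000 assumed tests they numbered 40 and 58. The mouse counts at FDR under 0.01 were 2873 and 4216. Mouse falls were listed in Acomys less often than mouse rises also at a minimum change of 1 or 3 and with no floor on expression. No paired analysis was possible because the tables hold no values per library. For the same reason the leave-one-out fits, the replicate block, other count tools, other pseudocounts and other splits of the samples were not run, and depth per library, which limits what could be listed, is unknown.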

Other observations

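The gene families and the loci without a symbol were chosen only after the results were seen. Across 20 gene families and 78 two-sided Fisher's exact tests of direction, solute carriers, the membrane transporters, fell in mouse by 90 to 30 on day 2 (adjusted p = 4.13e-12) and by 115 to 44 on day 5 (adjusted p = 6.81e-16). In Acomys they stood at 12 rises and 3 falls on day 2 (adjusted p = 0.373) and at 11 rises and 15 falls on day 5 (adjusted p = 0.000726). Cytochrome P450 genes, which oxidise drugs and lipids, fell by 22 to 5 on mouse day 2 (adjusted p = 0.000556), by 21 to 5 on mouse day 5 (adjusted p = 0.000492) and by 8 to 1 on Acomys day 5 (adjusted p = 0.000556). All 9 listed UDP glucuronosyltransferase genes fell on mouse day 5 (adjusted p = 0.00205), as did 10 of 11 acyl-CoA synthetase genes (adjusted p = 0.00503).

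Histocompatibility genes of the H2 complex rose 10 to 0 on mouse day 2 (adjusted p = 0.0382) and 20 to 0 on mouse day 5 (adjusted p = 0.000899). In Acomys the listed ones also all rose, 1 on day 2 and 6 on day 5 (adjusted p = 1 and 0.581). Counts that small could not pass this test in Acomys even with rises alone, so no contrast between the species follows from it. Integrin genes rose 10 to 0 on mouse day 2 (adjusted p = 0.0382) and 14 to 0 on mouse day 5 (adjusted p = 0.0111), and interleukin receptor genes 12 to 1 (adjusted p = 0.0493) and 17 to 1 (adjusted p = 0.0185). Keratin genes rose 10 to 0 on mouse day 2 (adjusted p = 0.0382) and 12 to 1 on day 5 (adjusted p = 0.0825), with 6 rises and 0 falls on each Acomys day; in the authors' deposited tables Krt14 was at 2.76 and 3.28 in mouse and 3.83 and 3.47 in Acomys. Whether a family differed between species was not tested.

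Acomys loci without a list symbol included a second NGAL locus at 7.64 on day 2 and 7.67 on day 5, CO3 loci (complement C3) at 6.84 and 6.55 and at 5.39 and 5.18, and a TRFL locus (lactoferrin) at 7.50 and 8.07 in the authors' deposited tables. A second SAA5 locus stood at 4.02 and 5.09 in the authors' deposited tables, above the 1.91 and 2.53 of the locus assigned to Saa1.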
